A study of Mus musculus with 4 samples.

How the data were processed

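The series holds 4 HTGTS libraries of genomic DNA from splenic B cells of C57BL/6J mice aged 12 weeks, 2 labelled Dfl and 2 labelled DKO. Per the labels' protocols, sonicated DNA was copied from a biotinylated primer at the 5′ side of Sμ, ligated to an adaptor, amplified by nested and indexing PCR, and sequenced on a MiSeq. The same protocols state that junctions of 2 independent experiments were combined, while each deposited file holds 1 library. Per the submitters' processing notes, positions are on mm10; the aligner, the junction caller and their versions are not given in the sources used here.

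Per the file headers, each deposited row is a sequenced read with its bait alignment, its prey alignment, the read positions at which these start and end, and the read sequence. The deposited genomic positions are 1-based coordinates without normalization, the positions on the read count from 1, and strands are given as 1 or -1; all of these were taken in that other unit, not as counts. Many reads repeat a junction, and the filter columns of the files were checked to be at 0 in every read.

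Distinct junctions were counted per library as combinations of prey chromosome, junction position, prey strand and bait end. The libraries held 1116, 877, 23486 and 36106 reads and 551, 457, 2271 and 4104 distinct junctions (Dfl 1, Dfl 2, DKO 1, DKO 2). Bait ends lay between 113425591 and 113425691 on chromosome 12. Gene positions came from a gene table of assembly GRCm38.p6, whose build is that of mm10. The Igh locus ran from 200 kb beyond Igha to the farthest annotated V segment (113056204 to 116009954). A switch window was the 10 kb upstream of a constant gene, and the Sμ window the 6 kb upstream of Ighm. Microhomology was the overlap of bait and prey alignments on the read, a direct join an overlap of 0, and an insertion a gap between them. Switch-like prey, defined after the data were seen, carried 5 or more switch pentamers per 100 prey bases.

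Shares were compared between summed junctions by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 18 comparisons. A share was called at an adjusted p under 0.05 when both DKO libraries also lay on the same side of both Dfl libraries. Log2 odds ratios are DKO over Dfl with 0.5 added to each count, and their 95% intervals come from the counts. Since the added 0.5 can turn the sign of a ratio of few junctions, directions were read from the shares. Intervals given for the share of a single library are exact (Clopper-Pearson), and a count of 0 was given the limit of 3 counts. Beside these, exact permutation tests over the 6 assignments of the libraries, limma on the logit of the library shares, and a Cochran-Mantel-Haenszel test with the replicate number as a block were run. Genes and 1 Mb bins outside Igh with 5 or more junctions were to be tested with limma and voom, with the junctions outside Igh as library size, and with limma-trend and Fisher's exact test beside it. Recurrence was the share of junctions in 10 kb bins with 2 or more, averaged over 100 draws to the size of the smallest library. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.

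Comparisons, windows, tests and most alternatives were chosen before the data were examined. The named genes were Tet2, Tet3 and Cd19; genes past an adjusted p of 0.05 in limma, at most 30; the 20 genes with the highest mean share in DKO with 2 or more junctions in each DKO library; the 10 highest in Dfl with 1 or more in each Dfl library; list members with 5 or more junctions; and all switch windows and receptor loci. Hfm1, Kif13b, Rarb, Gpc6, Npas3 and Clec2d fall outside this rule and were named after their values were seen. The gene lists were written before the data were examined: 48 AID off-target and translocation hotspot genes, 3 Cre targets and driver genes (Tet2, Tet3 and Cd19), 24 B cell lymphoma genes, 29 long neural genes, 16 T cell genes, 12 myeloid genes, and 13 germinal centre and plasma cell genes. All of their genes were found in the table.

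Alternatives set beforehand counted every read, or 1 junction per prey position and strand; kept prey of 30 bases or more; left out each library; used the replicate block; used limma on the library shares; and changed windows, distances, bins and the minimum microhomology. Alternatives added after the data were seen collapsed junctions within 10 bp, removed satellite junctions beside one with 10 times the reads, kept junctions with 2 or more reads, counted distinct fragment ends, used equal reads per library, left out junctions shared between libraries, left out switch-like prey, or kept prey of 100 bases or more.

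The share rule was tested on simulated data of the real depth. With no spread between libraries it called 0.222% of unchanged shares, and with the median observed spread it called 15.0%. A planted log2 odds ratio of 1 in the insertion share was called in 100% and 84% of simulations, with mean estimates of 0.99 and 1.01. For the 1 Mb bins at the real depth, limma with voom called 0 of 16 bins planted at 16-fold, and limma-trend called 11 of 15 and also 1 of 11 unchanged bins. At 60 times the depth, voom called 19 of 20 bins at 16-fold and 2 of 130 unchanged bins.

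The G-quadruplex motif share was not analysed here, since no genome sequence of the build was at hand. The gene table gives no strand, so distance to a gene start was replaced by distance to either gene end. The gene test at its planned minimum was not run, since 1 gene reached it.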

Results

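High-throughput genome-wide translocation sequencing (HTGTS) recorded the DNA joined to a break near the 5′ end of Sμ, the switch region upstream of Ighm, in B cells from the spleens of C57BL/6J mice aged 12 weeks. There were 2 libraries with the genotype label Dfl, taken here as the control, and 2 labelled DKO, which the series describes as CD19 Tet2/3 DKO. A switch junction links Sμ to a downstream switch region, and other junctions link it to the rest of Igh or to other chromosomes. The comparison asks whether B cells without Tet2 and Tet3 joined Sμ breaks to other places, or by other kinds of ends. Dfl 1 held 1116 junction reads at 551 distinct junctions, and Dfl 2 held 877 reads at 457. DKO 1 held 23486 reads at 2271 distinct junctions, and DKO 2 held 36106 reads at 4104. The files give neither the number of cells nor the total reads sequenced, so only shares of junctions were compared, and no break frequency per cell was estimated.

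Shares are of distinct junctions, each a combination of prey position, prey strand and bait end within a library. Of 18 shares compared, 11 differed between the groups by the rule fixed for them, a two-sided Fisher's exact test on summed junctions with Benjamini-Hochberg adjustment and no overlap between the libraries of the groups. An exact permutation test over the libraries cannot give a p under 0.333 with 2 against 2. In simulated data with the median spread seen between libraries of 1 group, 15.0% of unchanged shares passed this rule, so limma results on the library shares are given wherever they end a call. The labels do not say that the libraries of a group came from separate mice, so the limma and permutation p-values measure spread between these libraries, which may be technical. The Fisher p-values hold no such spread and treat junctions as independent. Collapsing junctions within 10 bp of each other left 434 of 551 and 382 of 457 in Dfl 1 and Dfl 2, but 759 of 2271 and 1123 of 4104 in DKO 1 and DKO 2. Near neighbours thus made up more of the distinct junctions in DKO, and the Fisher p-values and intervals on distinct junctions do not allow for this. Collapsing can also merge separate junctions that lie close together, more so where junctions are dense. The fullest 1 kb of Sμ held 175 and 125 junctions in Dfl 1 and Dfl 2, and 1032 and 1707 in DKO 1 and DKO 2. Collapsed values thus depend in part on depth, and cannot tell copies of 1 junction from separate neighbours. Intervals and limits cover counting error only, since the reads are PCR products without molecular identifiers.

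No junction fell in Tet2, Tet3 or Cd19, which allows up to 7.32% and 8.82% of the junctions outside Igh in Dfl 1 and Dfl 2, and up to 2.83% in each DKO library. These data do not show whether the Tet2 and Tet3 alleles were deleted.

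Downstream switch junctions in DKO were concentrated in Sγ2c, upstream of Ighg2c, with lower shares in Sα, Sγ1 and Sγ2b. The switch windows divide the same total, so a higher share in any window lowers the others, and their calls are not independent. Sγ2c held 89.7% ± 1.07 (SD, n = 2) of them in DKO and 41.4% ± 1.32 in Dfl. Both DKO libraries, at 90.4% (exact 95% binomial interval 87.8 to 92.6) and 88.9% (87.3 to 90.3), lay above both Dfl libraries, at 40.5% (34.7 to 46.5) and 42.4% (36.3 to 48.6). The log2 odds ratio was 3.56 (95% interval 3.25 to 3.87), from 2104 of 2356 junctions in DKO and 224 of 541 in Dfl (Fisher's exact test, adjusted p = 1.23e-116). Limma on the library shares gave an adjusted p of 0.00296. With neighbouring junctions collapsed, the Sγ2c share was 82.2% in DKO and 40.5% in Dfl (log2 odds ratio 2.76). The Sγ2c window runs from 113288933 to 113298932 on chromosome 12 (mm10). Its median junction lay at 113293471 and 113293683 in Dfl and at 113293309 and 113293026 in DKO. Of all junctions, Sγ2c held 31.1% ± 9.31 in DKO and 22.4% ± 2.67 in Dfl (n = 2 each, exact permutation p = 0.333). Among distinct junctions, this smaller gap rested on DKO 2, at 37.7%, since DKO 1 was at 24.5% and the Dfl libraries at 20.5% and 24.3%. On the same base of all junctions, the mean share of Sα was 10.5% in Dfl and 0.303% in DKO, and that of Sγ1 6.54% and 0.263%. Sγ2b held 9.17% and 1.31%, and Sγ3 5.17% and 1.63% (n = 2 each, exact permutation p = 0.333 for each window). Counted by distinct junctions on this base, the lower shares of the other windows were thus clearer than the higher share of Sγ2c. With neighbouring junctions collapsed, Sγ2c held 99 of 434 and 104 of 382 of all junctions in Dfl 1 and Dfl 2. It held 296 of 759 in DKO 1 and 612 of 1123 in DKO 2, so both DKO libraries then lay above both Dfl libraries.

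**Figure D1:**
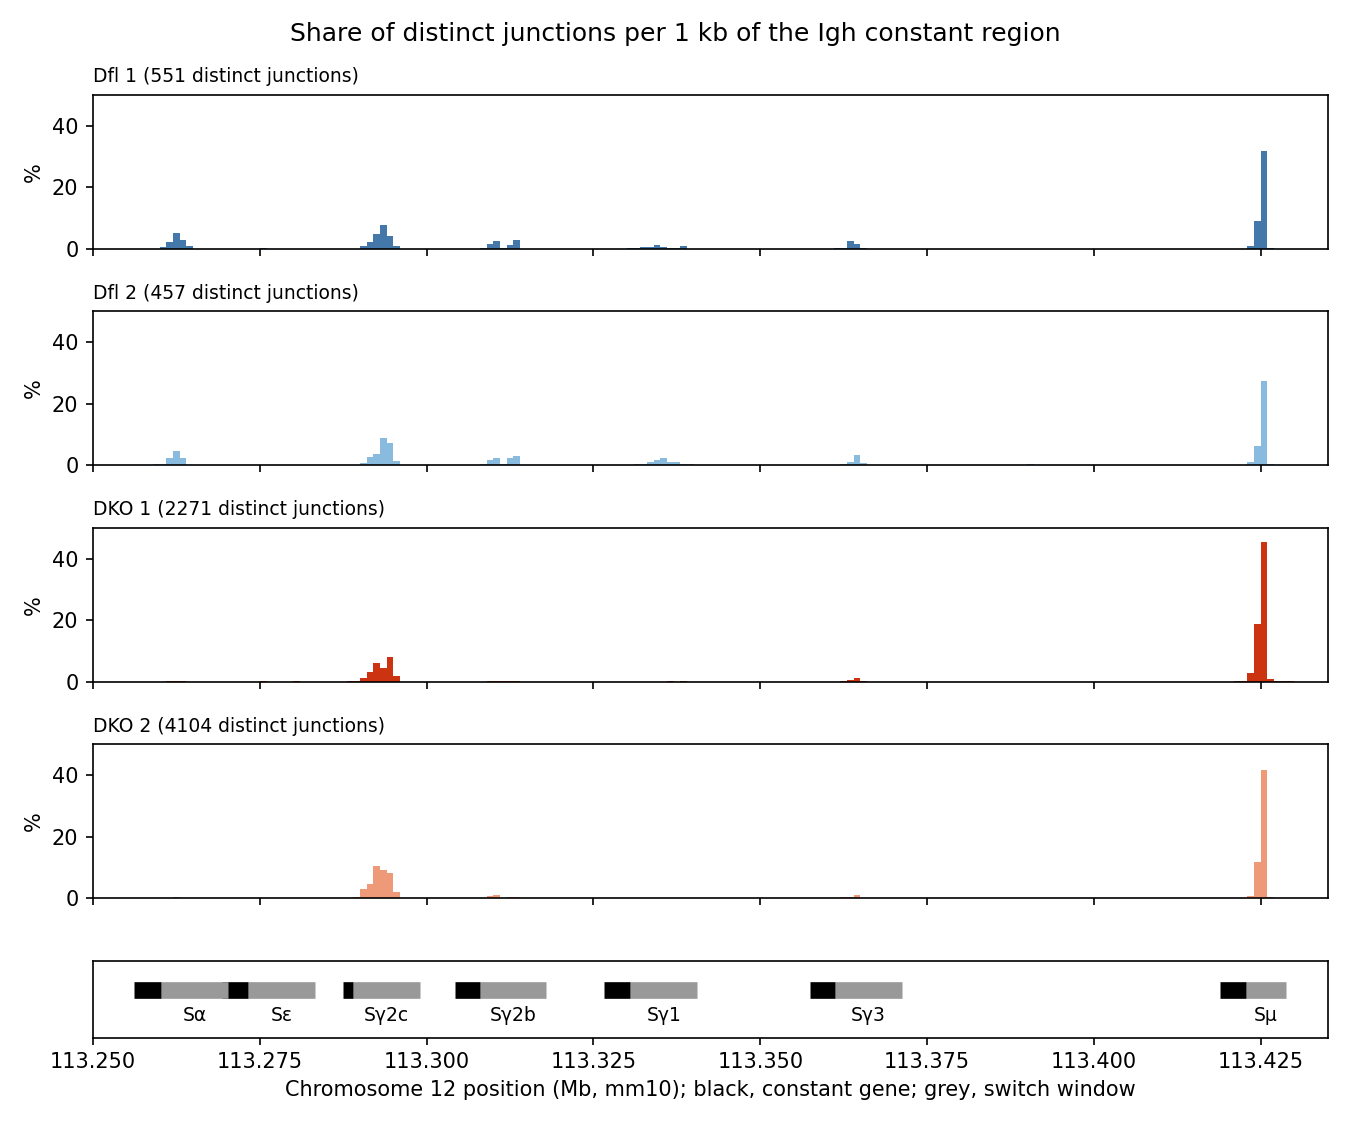
Share of each library's distinct junctions (%) per 1 kb of the Igh constant region, by position on chromosome 12 (Mb, mm10), with constant genes in black and switch windows in grey below. Junctions in Sα, Sγ1 and Sγ2b are visible in both Dfl libraries, while the DKO libraries are filled mainly at Sγ2c and Sμ.

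Sα held 19.7% ± 4.09 of downstream switch junctions in Dfl and 0.889% ± 0.120 in DKO (SD, n = 2 each). Its log2 odds ratio was -4.82 (95% interval -5.51 to -4.12; Fisher's exact test, adjusted p = 3.16e-60; limma, adjusted p = 0.00351). Sγ1 held 11.9% ± 4.19 in Dfl and 0.680% ± 0.502 in DKO, a log2 odds ratio of -3.94 (-4.68 to -3.21; exact adjusted p = 8.08e-31; limma, adjusted p = 0.0196). Sγ2b fell from 17.0% ± 0.290 to 3.35% ± 2.66, a log2 odds ratio of -2.21 (-2.64 to -1.78; exact adjusted p = 1.73e-21). The Sγ2b ratio was -3.72 without DKO 2, -3.83 when every read was counted and -1.485 with neighbouring junctions collapsed (17.0% against 6.79%), and limma on the library shares ended the call (adjusted p = 0.0787). Sγ3 fell from 9.60% ± 0.619 to 4.95% ± 1.72, a log2 odds ratio of -1.22 (-1.72 to -0.72; exact adjusted p = 9.93e-06). This Sγ3 call did not hold without DKO 2 (-0.69, adjusted p = 0.0592), with neighbouring junctions collapsed (-0.55, adjusted p = 0.131) or in limma (adjusted p = 0.0919). Sε held 2 of 541 junctions in Dfl (0.370%) and 9 of 2356 in DKO (0.382%), too few to show a difference; the log2 odds ratio of -0.20 (-2.21 to 1.82) takes its sign from the 0.5 added to each count. The Sε share was lower in DKO without Dfl 2 (0.717% against 0.382%) and without DKO 1 (0.370% against 0.287%). It was also lower with every read counted (0.446% against 0.0411%, log2 odds ratio -3.53, exact adjusted p = 0.000424), a count of PCR copies, and not called, since Dfl 2 held 0. The 0 of 262 Sε junctions in Dfl 2 allows up to 1.15%. Inverted junctions made up 3.88% ± 0.0890 of downstream switch junctions in Dfl and 4.35% ± 0.0515 in DKO, and did not pass (log2 odds ratio 0.14, exact adjusted p = 0.766). The inverted share passed as lower in DKO with every read counted, PCR copies included (3.66% against 1.63%, log2 odds ratio -1.21, exact adjusted p = 9.31e-06). It passed as higher with neighbouring junctions collapsed (4.19% against 7.79%, log2 odds ratio 0.92, exact adjusted p = 0.0175).

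**Figure D2:**
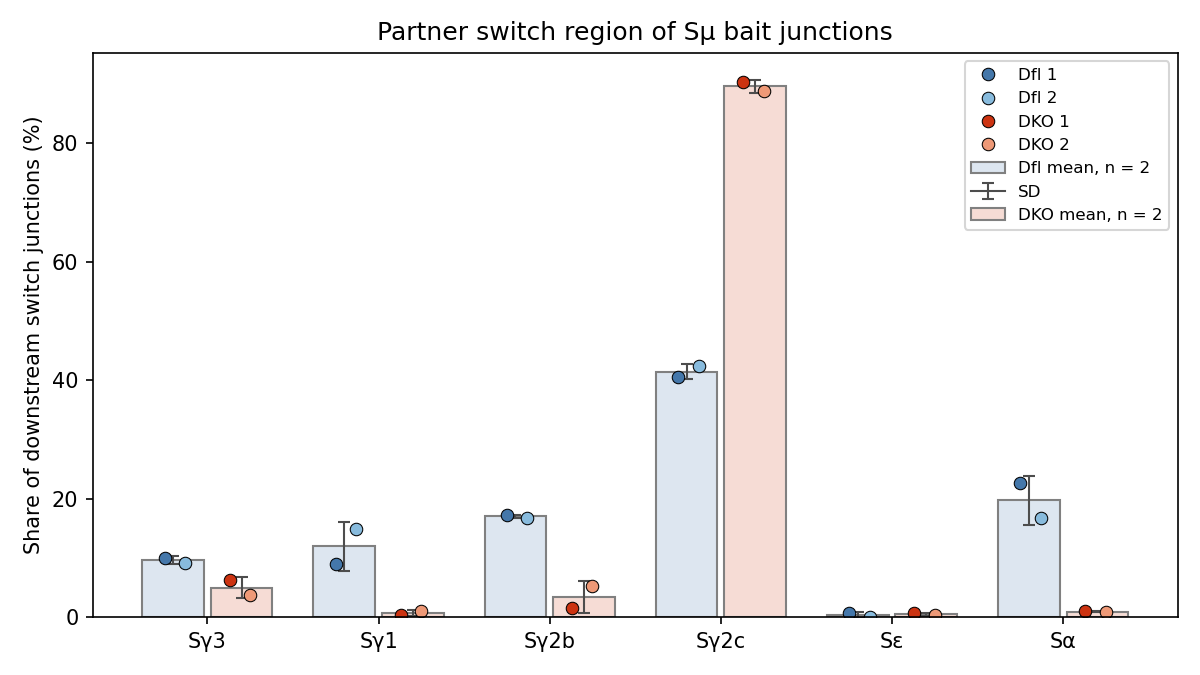
Share of downstream switch junctions (%) in each switch window, with a point per library, bars at the group means and error bars of 1 SD (n = 2 per group). Sγ2c lies near 90.4% and 88.9% in the DKO libraries and near 40.5% and 42.4% in the Dfl libraries.

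Within all junctions, those close to the Sμ bait were more frequent in DKO and those in downstream switch windows less frequent, but neither difference held under every way of counting junctions. Junctions within 10 kb of the bait made up 61.4% ± 9.37 in DKO and 38.3% ± 4.91 in Dfl (SD, n = 2 each). Their log2 odds ratio was 1.22 (95% interval 1.03 to 1.42; Fisher's exact test, adjusted p = 1.46e-34). Downstream switch windows held 34.8% ± 10.8 in DKO and 54.0% ± 4.73 in Dfl, a log2 odds ratio of -0.98 (-1.18 to -0.79; exact adjusted p = 6.03e-23). With junctions within 10 bp of each other collapsed, the share close to the bait was 29.9% in Dfl and 30.4% in DKO, and the downstream share was 61.4% and 58.7%. These collapsed shares also depend on how densely the junctions lay near the bait. With every read counted, the downstream share was 56.2% in Dfl and 57.2% in DKO, and the log2 odds ratio close to the bait was 0.19. Both calls held with 2 or more reads per junction (log2 odds ratio 1.63 close to the bait and -1.49 downstream). They also held by fragment ends (0.71 and -0.49) and at equal reads per library (0.97 and -0.67). In all, 16 of 19 alternatives close to the bait and 14 of 18 downstream kept the direction and the call. Without DKO 2 the downstream ratio was -1.64, and without DKO 1 it was -0.65. Limma on the library shares ended both calls (adjusted p = 0.0823 close to the bait and 0.114 downstream).

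Junction ends in DKO carried inserted bases more often and microhomology less often. Insertions, counted as any gap between the bait and prey alignments and so including mismatched bases at the junction, were present at 44.1% ± 0.201 of junctions in DKO and 23.5% ± 0.156 in Dfl (SD, n = 2 each). The log2 odds ratio was 1.36 (95% interval 1.14 to 1.58; Fisher's exact test, adjusted p = 1.84e-36; limma, adjusted p = 0.00960). Microhomology of 1 base or more was present at 38.3% ± 0.342 in DKO and 59.9% ± 2.76 in Dfl, a log2 odds ratio of -1.27 (-1.47 to -1.08; exact adjusted p = 2.67e-37; limma, adjusted p = 0.0134). Direct joins made up 17.5% ± 0.543 in DKO and 16.5% ± 2.60 in Dfl and did not pass (log2 odds ratio 0.11, and -0.10 without Dfl 1; exact adjusted p = 0.473). Within Sγ2c alone, insertions were present at 15.9% and 21.6% of junctions in the Dfl libraries and at 44.2% and 46.1% in the DKO libraries. The median insertion in Sγ2c was 3.5 and 3 bases in Dfl, and 5 bases in both DKO libraries. Within the Sμ window, insertions were present at 18.7% and 20.8% in Dfl and at 42.9% and 42.0% in DKO. Outside Igh neither difference passed (log2 odds ratio 0.50 for insertions and -0.20 for microhomology). The differences were smaller when every read was counted (0.62 for insertions; -0.33 for microhomology, where the libraries of the groups overlapped), and the insertion ratio was 0.87 at equal reads per library.

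**Figure D3:**
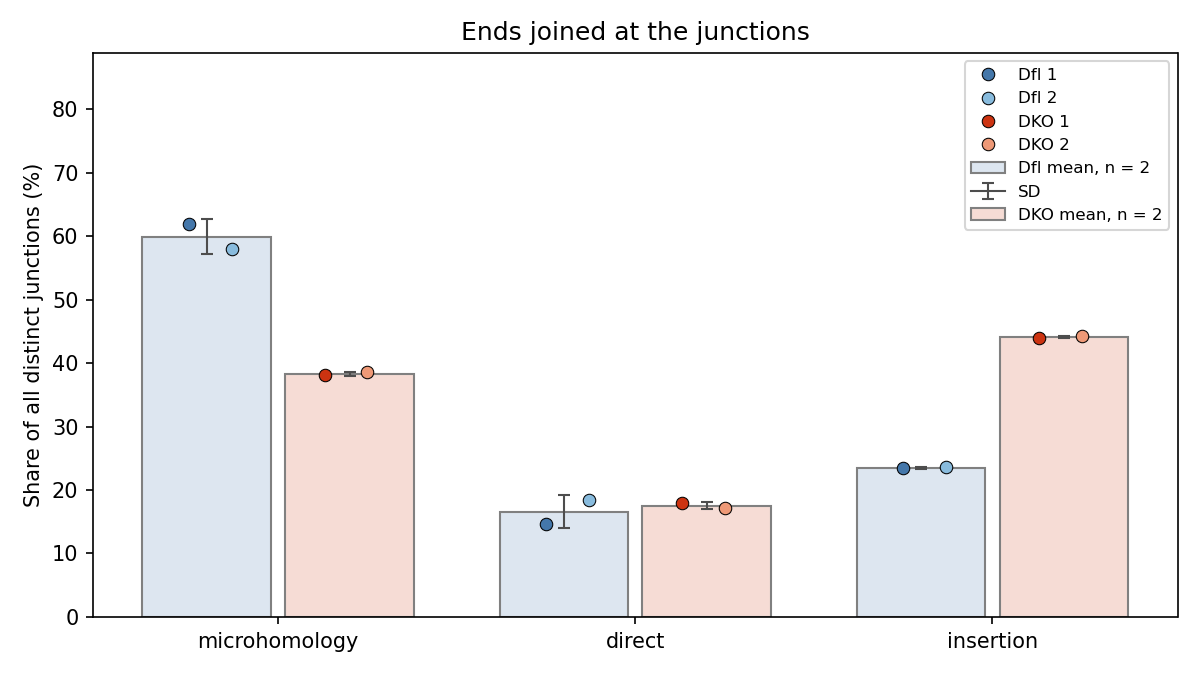
Share of all distinct junctions (%) with microhomology, a direct join or an insertion, with a point per library, bars at the group means and error bars of 1 SD (n = 2 per group). Insertions lie at 44.0% and 44.3% in the DKO libraries and at 23.4% and 23.6% in the Dfl libraries.

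Junctions outside Igh were a smaller share of distinct junctions in DKO, a difference that turned when neighbouring junctions were collapsed. They made up 7.44% ± 0.00084 in Dfl and 3.63% ± 1.47 in DKO (SD, n = 2 each), or 75 of 1008 against 212 of 6375 junctions. The log2 odds ratio was -1.23 (95% interval -1.62 to -0.84; Fisher's exact test, adjusted p = 2.15e-08). Junctions on other chromosomes made up 6.73% ± 0.235 in Dfl and 3.36% ± 1.41 in DKO, a log2 odds ratio of -1.20 (exact adjusted p = 2.14e-07). With neighbouring junctions collapsed, the share outside Igh was 8.33% in Dfl and 10.2% in DKO (log2 odds ratio 0.32, exact adjusted p = 0.245). Collapsing merges more where junctions are dense, as within Igh in the DKO libraries, so this turn may stem in part from depth. The ratio outside Igh was -2.40 with every read counted and -0.72 without DKO 2, and -0.67 on other chromosomes without DKO 2. Limma on the library shares ended both calls (adjusted p = 0.0919 and 0.0975). A higher share on other chromosomes in DKO was not called under any of the ways of counting junctions that were tried. With neighbouring junctions collapsed, that share was 7.48% in Dfl and 9.40% in DKO (exact adjusted p = 0.241). Since these shares also depend on the number of junctions within Igh, they cannot show whether translocations per cell rose or fell.

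Of junctions outside Igh, 54.0% ± 9.84 in Dfl and 45.8% ± 2.00 in DKO lay in an annotated gene (SD, n = 2 each; Fisher's exact test, adjusted p = 0.339). Those within 2 kb of a gene end made up 17.9% ± 8.01 and 12.7% ± 2.00 (exact adjusted p = 0.402), and the direction turned under 7 of 18 alternatives, among them without Dfl 2 (12.2% against 12.7%). Antigen receptor loci other than Igh held 0 of 75 junctions in Dfl and 5 of 212 in DKO (exact adjusted p = 0.402). In DKO 1, 4 of these lay in Igk on chromosome 6, and in DKO 2, 1 lay in Igl on chromosome 16; no library had a junction in Tra and Trd, Trb or Trg. With every read counted the log2 odds ratio was 3.45 and the rule was passed, but those reads are PCR copies of the same 5 junctions and not independent.

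Single genes and 1 Mb bins outside Igh held too few junctions for firm comparisons. Only Kcnj6 (gene 16522; chromosome 16, 94744980 to 94997696) reached 5 junctions, with 0 and 0 in Dfl and 2 and 4 in DKO, all between 94869461 and 94869479. Nrxn1 (gene 18189; chromosome 17, 90033644 to 91093159) had 1 junction in each Dfl library and 0 in each DKO library. Without a minimum count, limma with voom called 3 of 112 genes (Hfm1, Kif13b and Nrxn1, lower in DKO; 24 at an unadjusted p under 0.05). The limma-trend fit called 3 genes (Kcnj6 and Rarb higher and Nrxn1 lower, 4 unadjusted), and Fisher's exact test called 0 (0 unadjusted). All 6 junctions in Kcnj6 and all 4 in Rarb were switch-like prey, for which misplaced switch region reads cannot be told apart from true junctions. Nrxn1 was in both sets of calls; its 2 junctions, as those of Hfm1 and Kif13b, do not allow a firm difference. Among 6 bins of 1 Mb with 5 or more junctions, limma with voom called 0 (1 unadjusted), Fisher's exact test called 0 (0 unadjusted), and limma-trend called 3, all higher in DKO. These 3 bins begin at 16 Mb on chromosome 11, 94 Mb on chromosome 16 and 132 Mb on chromosome 4. All 7 junctions of the chromosome 11 bin and all 6 of the chromosome 16 bin were switch-like prey, against 0 of 5 in the chromosome 4 bin. Of those 5, however, 4 came from DKO 2 and lay between 132885399 and 132885402, so they may be copies of 1 junction. Without DKO 1, voom called the same 3 bins, each on 4 junctions of DKO 2 against 0 in both Dfl libraries; that fit assumes that the lone DKO library varies like the Dfl libraries. Junctions in 10 kb bins with 2 or more made up 17.2% ± 13.1 in Dfl and 24.8% ± 7.78 in DKO at 34 junctions per library (n = 2 each, exact permutation p = 0.667); without Dfl 1 the difference was -1.71 percentage points, and without Dfl 2 it was 16.9. Both DKO libraries lay above both Dfl libraries with neighbouring junctions collapsed (0% in Dfl, 17.7% in DKO), with 1 junction per prey position (1.72% and 17.9%) and with every read counted (45.6% and 62.3%), each with the smallest exact permutation p of 0.333. Without switch-like prey the difference was -7.52 percentage points.

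The fixed gene lists together held 2 of 75 junctions outside Igh in Dfl and 2 of 212 in DKO (log2 odds ratio -1.52, Fisher's exact test, adjusted p = 0.388), all in long neural genes: Nrxn1 in Dfl, Gpc6 in DKO 1 and Npas3 in DKO 2. Limma called this share lower in DKO (adjusted p = 0.0115), on those 4 junctions. The 48 AID off-target and translocation hotspot genes and the 24 B cell lymphoma genes held 0 junctions in every library. The lists of 16 T cell genes, 12 myeloid genes and 13 germinal centre and plasma cell genes also held 0. At 5 kb beyond gene limits, 1 junction in DKO 2 fell at Clec2d, a hotspot gene.

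Reads were concentrated on few junctions in DKO. The most-read junction held 3.85% and 3.65% of reads in Dfl 1 and Dfl 2 (exact 95% binomial intervals 2.80 to 5.16 and 2.51 to 5.11), at 113425442 on chromosome 12 in Sμ in both. It held 45.3% (44.6 to 45.9) of reads in DKO 1, at 113292210 in Sγ2c, and 11.1% (10.8 to 11.5) in DKO 2, at 113293719 in Sγ2c. These intervals treat reads as independent, though many are PCR copies. Of the distinct fragment ends, the most-read junction held 34 of 867 and 28 of 708 in Dfl 1 and Dfl 2. It held 50 of 5668 in DKO 1 and 335 of 12043 in DKO 2, so the concentration in DKO was seen in reads and not in fragment ends. Fragment ends were counted as distinct end positions on the read, so their number per junction is limited by the read length. A much-read junction cannot gain ends in step with its reads. Counts of ends, also at equal numbers, thus cannot show whether few junctions dominated the DNA of the DKO cells. At 877 reads per library, the effective number of junctions was 179 in each Dfl library, 4.77 in DKO 1 and 37.2 in DKO 2 (n = 2 each, exact permutation p = 0.333). At 708 distinct fragment ends per library it was 189 and 182 in Dfl and 154 and 183 in DKO (exact permutation p = 0.667).

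**Figure D4:**
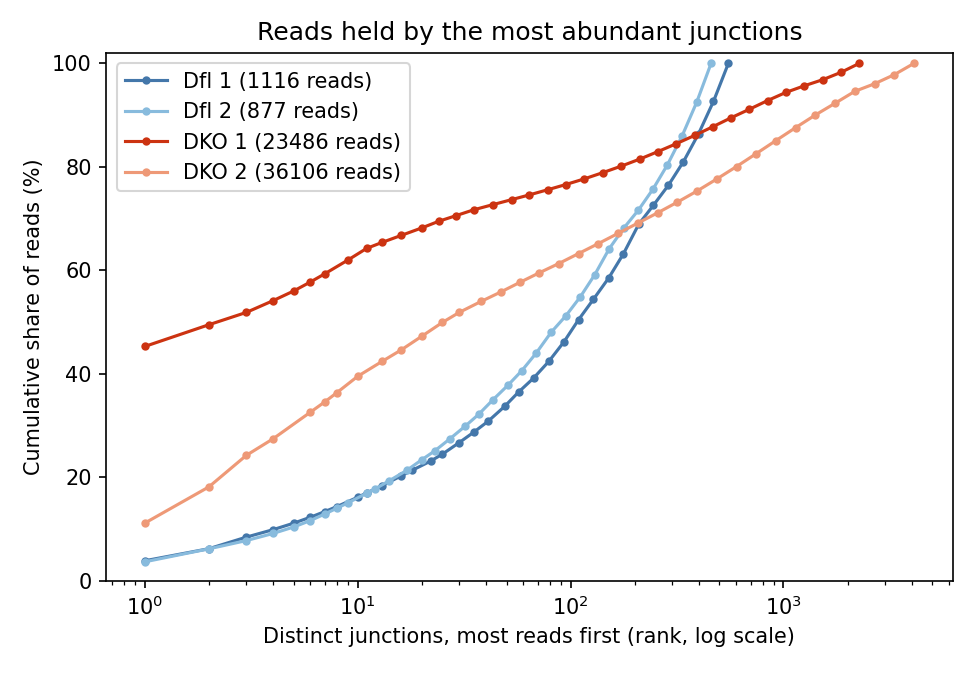
Cumulative share of reads (%) against the rank of each junction by reads (log axis), with a line per library. The first junction holds 45.3% of reads in DKO 1 and 11.1% in DKO 2, against 3.85% and 3.65% in the Dfl libraries.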

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

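The sequence composition of the prey, the mismatch rates and the tests of explanations in this part were all chosen only after the results were seen.

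Prey outside Igh that resembled switch sequence, a signal outside the planned comparisons, was above the level of the control libraries in both DKO libraries. Such prey made up 30.2% of junctions outside Igh in DKO 1 (32 of 106) and 55.7% in DKO 2 (59 of 106). In Dfl they made up 4.88% (2 of 41) and 5.88% (2 of 34), and Fisher's exact test on the summed junctions gave p = 1.0e-10. The 95 junctions lay in 34 bins of 10 kb, 62 of them in bins with such prey in 2 or more libraries. The fullest was on chromosome 19 between 35276441 and 35276573 (16 junctions), then chromosome 12 between 62282329 and 62282407 (13), chromosome 11 between 16295122 and 16295206 (7), and Kcnj6 on chromosome 16 (6).

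No table excludes a technical explanation of this prey. At equal reads per library its share fell to means of 23.3% ± 15.0 and 30.1% ± 15.6 (SD over draws) in DKO 1 and DKO 2, against 4.59% and 5.88% in Dfl. The mean difference was 21.5 percentage points, but 16 of 99 draws gave 10 or less, so read depth cannot be told apart from a difference between the groups. Switch region reads aligned to the wrong place cannot be told apart from true junctions at switch-like repeats. Switch-like prey carried a median of at least 3.86 more mismatches per 100 bases than other prey outside Igh in each DKO library. The means were 5.90 against 3.80 in DKO 1 and 7.44 against 2.70 in DKO 2. A permutation test on the difference in means gave p = 0.0623 in DKO 1 and 2.0e-05 in DKO 2, the smallest these permutations can give. The test treats junctions as independent, though many lay close together at the same sites. Depth and misplaced reads may account for this prey, and the genotype stays open and untested.

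Mismatches per 100 bait bases beyond the primer, in sequence outside the planned comparisons, were 1.16 in DKO 1 and 1.46 in DKO 2, above 0.973 and 0.941 in Dfl 1 and Dfl 2 (n = 2 each, exact permutation p = 0.333). These rates are over all reads, so the most-read junctions weigh most. Averaged over junctions with 5 or more reads, they were 1.39 and 1.46 in DKO and 0.567 and 0.536 in Dfl. These means rest on 444 and 949 junctions in DKO 1 and DKO 2, but on 32 and 29 in Dfl 1 and Dfl 2. At such unlike depth, the minimum of 5 reads may keep unlike sets of junctions. Within the primer, the rates over all reads overlapped, at 0.0652 and 0.0568 in DKO and 0.0764 and 0.0515 in Dfl. In Sγ2c junctions with 5 or more reads, prey carried a mean of 1.08 and 1.23 mismatches per 100 bases in DKO 1 and DKO 2. These lay above 0.888 and 0.270 in Dfl 1 and Dfl 2, from 172 and 431 junctions in DKO and 13 and 10 in Dfl. After collapsing neighbouring junctions the libraries overlapped, at 1.14 and 1.59 in Dfl and 1.55 and 1.56 in DKO.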

How the results depend on the processing

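Collapsing neighbours, leaving out junctions shared between libraries, keeping junctions with 2 or more reads or prey of 100 bases or more, removing satellites or switch-like prey, counting fragment ends and equalising reads were chosen only after the data were seen; the other alternatives were planned. Values are log2 odds ratios, DKO over Dfl, unless stated, and directions are those of the shares. Sγ2c (2.76 to 4.27), Sα (-6.83 to -3.88) and Sγ1 (-5.05 to -3.12) kept their direction and their call in all 18 alternatives run for each. The genic share outside Igh kept its direction without a call in all 17 (-0.87 to -0.016). Over all results, 298 alternatives turned no tested share and changed no call, and moved recurrence by less than the SD pooled over the groups (though from 7.59 percentage points to 16.7 with every read, 16.2 with 1 junction per prey position and 17.7 collapsed, and with its sign turned without Dfl 1); 20 ended a call, 24 turned the direction, 3 gave a new call in the same direction and 6 moved an untested value or a count.

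With neighbours collapsed, the direction turned outside Igh (0.32) and on other chromosomes (0.35), calls ended downstream (-0.16), close to the bait (0.036) and at Sγ3 (-0.55), and inverted junctions gained a call (0.92). With every read counted, direction turned downstream (0.058), for Sε (-3.53), inverted (-1.21) and direct (-0.23) joins and near gene ends (0.20); calls ended close to the bait (0.19) and for microhomology (-0.33), and receptor loci gained one on PCR copies of 5 junctions (3.45). With 1 junction per prey position, calls ended on other chromosomes (-0.54) and downstream (-0.59). With 2 or more reads, calls ended outside Igh (-0.99), on other chromosomes (-0.95) and at Sγ3 (-0.81), and Sε (-1.99) and the share near gene ends (0.39) turned. The cause was not tested.

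Limma on the library shares, with 2 libraries per group, ended the calls outside Igh (-1.17), on other chromosomes (-1.13), downstream (-1.16), close to the bait (1.37), at Sγ3 (-1.08) and at Sγ2b (-2.81). It called the gene lists (-1.52). Taking the numbers in the labels as paired, with a replicate block, left the same number of calls, 11, and gave 2 called 1 Mb bins; replicate numbers correlated at -0.0942 over 19 bins of Igh, so they give no sign of pairing.

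At equal reads, the Sγ3 call ended (-0.77) and the share near gene ends turned (0.30). Near gene ends, prey of 30 bases or more (0.083) or 100 or more (1.10) and removal of switch-like prey (0.12) turned the direction as well. Sε also turned with prey of 30 bases or more (-0.35) or 100 or more (-1.62), by fragment ends (-1.80) and without shared junctions (-0.35), inverted joins by fragment ends (-0.24), and direct joins outside Igh (-0.74) and in downstream windows (-0.15). Outside Igh alone, with fewer junctions, calls ended for microhomology (-0.20) and insertions (0.50). Recurrence without switch-like prey moved to -7.52 percentage points. Limma-trend called 3 bins of 1 Mb at each pseudocount of 0.5, 0.1 and 2, against 0 by voom. The cause was not tested.

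Leaving out 1 library gave -1.46 to -0.69 at Sγ3 (call lost without DKO 2), -1.15 to 1.09 at Sε (turned without Dfl 2 and without DKO 1), -1.11 to -0.024 near gene ends (turned without Dfl 2), -0.10 to 0.29 for direct joins, -1.60 to -0.72 outside Igh, -1.58 to -0.67 on other chromosomes, -1.64 to -0.65 downstream, 0.95 to 1.76 close to the bait, -3.72 to -1.89 at Sγ2b, -1.71 to 16.9 percentage points for recurrence, and 0 to 3 called bins (3 without DKO 1, where the lone DKO library is assumed to vary like Dfl). Not run, for want of genes or bins: gene tests with a minimum count, and bins with 10 or more junctions or without switch-like prey. The motif share was not run either. Depth limits results outside Igh, where Dfl had 41 and 34 junctions.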

Other observations

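The tests of explanations and the junction overlaps in this part were chosen only after the results were seen; the Sγ2c and insertion shares themselves were planned.

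Sγ2c held a higher share of downstream switch junctions in both DKO libraries. The groups still differed by 42.8 percentage points after junctions within 10 bp were collapsed. This argues against such neighbours as the whole cause, but copies of 1 junction further apart were not merged. The tables also argue against read depth, since the groups differed by 47.5 points at equal reads per library and by at least 44.3 in each draw. Reads shared between Sγ2b and Sγ2c are excluded as the whole cause, since the summed share of both differed by 34.6 points (58.4% in Dfl, 93.0% in DKO). Sγ2c junctions with 10 or more reads lay in 32 bins of 100 bp in DKO 1 and 52 in DKO 2. This argues against a single expanded clone in each DKO library. It does not exclude one, since copies of 1 junction aligned to several bins were not merged. Several expanded clones, a different state of the cells before isolation, and the genotype stay open and untested. The labels do not say whether the cells were stimulated, so a difference in their treatment after isolation stays open as well.

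Insertions were more frequent at junctions of both DKO libraries. The shares still differed by 16.9 percentage points after junctions within 10 bp were collapsed, which argues against such neighbours as the whole cause. Copies of 1 junction whose alignments ended further apart were not merged, so the test cannot decide on those. In Sγ2c, gaps of more than 10 bases were present at 14.7% and 15.0% of junctions in DKO and at 3.54% and 3.60% in Dfl. A different mix of switch regions is excluded as the whole cause, since the shares differed by 26.4 points within Sγ2c. Read depth may account for part of it, since the log2 odds ratio was 0.87 at equal reads per library and 1.36 at full depth. Mismatched bases beside the junction cannot be told apart from inserted bases: the shares differed by 18.6 points among reads without mismatches inside the alignments, but a mismatch at the junction itself would end an alignment and lie in the gap. The genotype and library preparation stay open and untested.

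The most-read junction of DKO 1 had 10634 reads at 50 distinct fragment ends, or 213 reads per end, against 4.91 per end at its second most-read junction. It had 0 reads in DKO 2 and 1 read in each Dfl library. Of 7117 distinct junctions over the libraries, 227 occurred in 2 or more, and 12 occurred in all 4, each of them in the Sμ window. These 12 had a median microhomology of 9.5 bases, against 0 for Sμ junctions found in 1 library, and held 14.2%, 12.9%, 0.264% and 0.235% of reads in Dfl 1, Dfl 2, DKO 1 and DKO 2. Junctions shared by fewer libraries were not confined to Sμ. Leaving out all shared junctions moved the Sγ2c share of downstream switch junctions from 41.4% to 35.8% in Dfl, and from 89.3% to 89.2% in DKO. Why these junctions were shared was not tested.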
